A study of Mus musculus with 2 samples.

How the data were processed

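Liver transcripts were measured in ICR mice, an outbred stock, that received either a basal diet or the same diet with 500 ppm diosgenin, a plant steroidal sapogenin, for 4 weeks from the age of 9 weeks. Each diet was represented by 1 Affymetrix array, and each array carried RNA pooled from the livers of 3 mice. Per the labels' protocols, aliquots of 5 µg of pooled total RNA were labelled with biotin. The deposited values were array intensities on a linear scale, 1 signal for each of 45101 probe sets, and GCOS, the Affymetrix operating software, is named in the submitters' processing notes without a version. The summary algorithm, the target of the scaling and the detection calls are not given in the sources used here. Both arrays had a 2% trimmed mean of 96.9, which shows a common global scaling in the deposited intensities. The median signal was 17.1 on the control array and 17.0 on the diosgenin array, and no value was negative.

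Probe sets were named from the platform annotation of the array, and gene identifiers were matched to the RefSeq gene table of the mouse assembly GRCm38.p6, used for names only. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 were unnamed here, among them most control probe sets. The control probe sets for Actb, Gapdh, Pcx and Tfrc carry a symbol, and that of the 5′ end of Gapdh represents this gene. Of those with 1 symbol, 34754 matched the RefSeq table, and 0 symbols differed between both sources. Probe sets with several symbols or none were left out of the gene values. Of the 1736 such probe sets above the signal filter, 16 were at least 2-fold higher and 26 at least 2-fold lower on the diosgenin array.

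Signals under a floor of 10.7, the 40th percentile of all signals of both arrays, were set to the floor before log2 was taken. A gene was represented by its probe set with the highest mean linear signal, and was kept where that mean reached 28.4, the 60th percentile of all probe sets. This left 9732 of 18195 genes. The value for each gene was the log2 ratio of the diosgenin array over the control array. No p-value, standard error or interval was computed, since each diet had 1 array and neither the spread between mice nor that between pools can be had from a pool. The number of arrays therefore limits the precision. Per the labels, cages held 3 mice, and whether each diet was a single cage is not given, so an effect of the cage and one of the diet may not be separable. Genes at least 2-fold apart were counted as a description of these 2 arrays.

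The repeat measurement inside an array came from genes with several probe sets. Among 4079 such genes above the filter, the other probe sets had the same sign as the chosen one in 62.9%, and log2 ratios of probe sets of the same gene had a standard deviation of 0.28. This spread can also hold differences between the transcripts that probe sets read, and contains no spread between mice. The spread of log2 ratios depended on signal. The central 95% of genes reached from −0.95 to 0.83 among the 2433 dimmest genes and from −0.47 to 0.44 among the 2433 brightest.

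Before the data were examined, 23 gene lists and 14 lists of cell type markers were fixed, together with the signal filter, the floor, the counting threshold and the rule for naming genes. For each list the median log2 ratio of its genes above the filter was set against 10000 random lists of the same size, matched on mean signal in 20 bins. A list whose median lay outside the central 95% of the random lists is said to stand apart. About 1.15 of the 23 gene lists would do so by chance if genes were independent. Genes of a pathway vary together, so more could, and the percentile describes these arrays and is not a test of the diet. Lists with under 5 genes above the filter have values and no percentile.

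Genes were named by these rules. The 12 highest and 12 lowest log2 ratios were named among genes with both signals above the floor, leaving out provisional symbols and genes whose other probe sets had the opposite sign or a median under 0.5 in size. Genes with a signal under the floor, up to 5 per direction, were given as bounds. Up to 4 genes with the largest absolute log2 ratio were named per list, up to 8 where the list stood apart, and up to 3 per marker list. Genes of multigene families read by probe sets ending in _x_at or _s_at, which can bind several transcripts, are called uncertain. The rule passed over 2 genes because their probe sets disagreed and 0 because of provisional symbols.

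The procedure was tested on simulated pairs of arrays in which log2 noise was normal with the spread of the bulk of the real ratios. Of 9539 unchanged simulated genes, 66 were counted as at least 2-fold apart. The share of changed genes counted was 2.04% for a simulated 1.5-fold change, 46.9% for 2-fold, 98% for 3-fold and 100% for 4-fold. Of 400 lists without a shift 18 stood apart, and of 100 lists of 20 genes shifted by 0.2 on the log2 scale 86 did. The simulation contains no spread between mice.

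Alternatives planned in advance were centred ratios, quantile normalization, removal of a loess trend on signal, other floors, no filter or a filter at the 75th percentile, the median of a gene's probe sets, the omission of probe sets ending in _x_at, _s_at or _a_at, other fold thresholds, the list mean in place of the median, and the omission of genes found in several lists. Each was run with the other choices kept. After the data were seen, the percentiles of the lists were also taken from 20 other draws of the random lists. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.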

Results

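The question addressed was how a diet with 500 ppm diosgenin, fed for 4 weeks, affects transcript levels in mouse liver. The data were 2 arrays of 45101 probe sets each, 1 for the control diet and 1 for the diosgenin diet, each from liver RNA pooled from 3 mice at 13 weeks of age. There were no replicate arrays. Cages held 3 mice, and the labels do not say whether each diet was 1 cage, so cage and diet may coincide. Every difference below is therefore a difference between 2 pools, without a test, and the words higher and lower always describe the diosgenin array relative to the control array. Signals above the floor of 10.7 made up 59.9% of the control array and 60.1% of the diosgenin array, and the highest signals were 12546 and 12823.

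The arrays were alike for most genes. Of 9732 genes above the signal filter, 93.6% were within 1.5-fold of each other, and log2 signals correlated across genes at r = 0.983, where genes are not independent replicates. At least 2-fold higher signals were found for 54 genes and at least 2-fold lower signals for 83, together 1.41% of genes. Of these 137 genes, 82 were among the 2433 dimmest, with mean signals of 28.4 to 68.0, where the spread was widest. In the simulation, 66 of 9539 unchanged genes were also counted as at least 2-fold apart. Part of the 137 may therefore be no more than the tails of the spread of the bulk of genes. The counts depended on the filter, with 180 higher and 218 lower without it and 19 and 32 with the filter at the 75th percentile. Single log2 ratios under 0.28 in size are within the standard deviation between probe sets of the same gene. Where genes with such ratios are named below as higher or lower, the difference may be no more than measurement spread.

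The 12 highest ratios included the carboxylesterase Ces5a, 6.14-fold higher with signals of 18.7 and 115, and the clock-controlled transcription factor Dbp, 5.27-fold higher with 39.99 and 211. Ces5a was read by a probe set that can bind several family members and is uncertain. The second Dbp probe set gave a log2 ratio of 2.62. Rgs16, a regulator of G protein signalling, was 4.29-fold higher, the trefoil factor Tff3 4.11-fold and Trim34a 3.86-fold. Hamp2, a hepcidin family gene, was 3.43-fold higher at a much brighter level, 603 against 2068, and is uncertain for the same reason as Ces5a. Marco, a macrophage scavenger receptor, was 3.39-fold higher, Tcf24 3.25-fold, the cell cycle kinase Cdk2 3.09-fold, Wipf3 2.96-fold, the class II antigen-presenting gene H2-Eb1 2.68-fold and the chemokine Cxcl9 2.64-fold. Trim34a, Marco, Tcf24 and Wipf3 were dim, and with a floor at the 60th percentile their log2 ratios were 0.67, 0.67, 1.19 and 0.78. At that floor those of Ces5a and Rgs16 were 2.01 and 1.63.

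The lowest ratio among genes measured on both arrays was that of Egr1, an immediate early transcription factor, at 545 on the control array and 63.1 on the diosgenin array, 8.63-fold lower. Fam25c followed at 6.48-fold lower and A2ml1, a relative of alpha-2-macroglobulin, at 5.00-fold lower. The sulfate transporter Slc26a2 was 4.20-fold lower, Sh2d3c 4.15-fold, Nucb2 3.91-fold, Igsf23 3.81-fold and the sphingosine phosphate receptor S1pr5 3.59-fold. Phgdh, the enzyme that opens serine synthesis, was 3.53-fold lower by a probe set shared between transcripts. Creld2, an endoplasmic reticulum protein, was 3.40-fold lower at 1449 against 426, Csrnp1 3.34-fold and Clec2h 3.28-fold. Signals on the diosgenin array were under the floor for Snrnp25, Ccdc180 and Cyp26b1, a retinoic acid hydroxylase, which gives bounds of at least 7.41-fold, 6.80-fold and 6.56-fold lower. With a floor at the 60th percentile, the log2 ratios of Slc26a2, Sh2d3c, Igsf23 and Csrnp1 were −0.94, −0.89, −1.17 and −0.70, and the bounds for Snrnp25, Ccdc180 and Cyp26b1 became −1.48, −1.36 and −1.31. Nucb2 and Phgdh were then at −1.49 and −1.52. With a floor at the 20th percentile Snrnp25 and Cyp26b1 were at −3.65 and −3.27. The median of the Clec2h probe sets was −1.10 and that of the Slc26a2 probe sets −1.44. Hsd17b13 and Fen1 would have ranked among these genes by size, but their probe sets disagreed, at 2.26 and −0.80 for Hsd17b13 and −2.15 and 0.17 for Fen1.

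**Figure D1:**
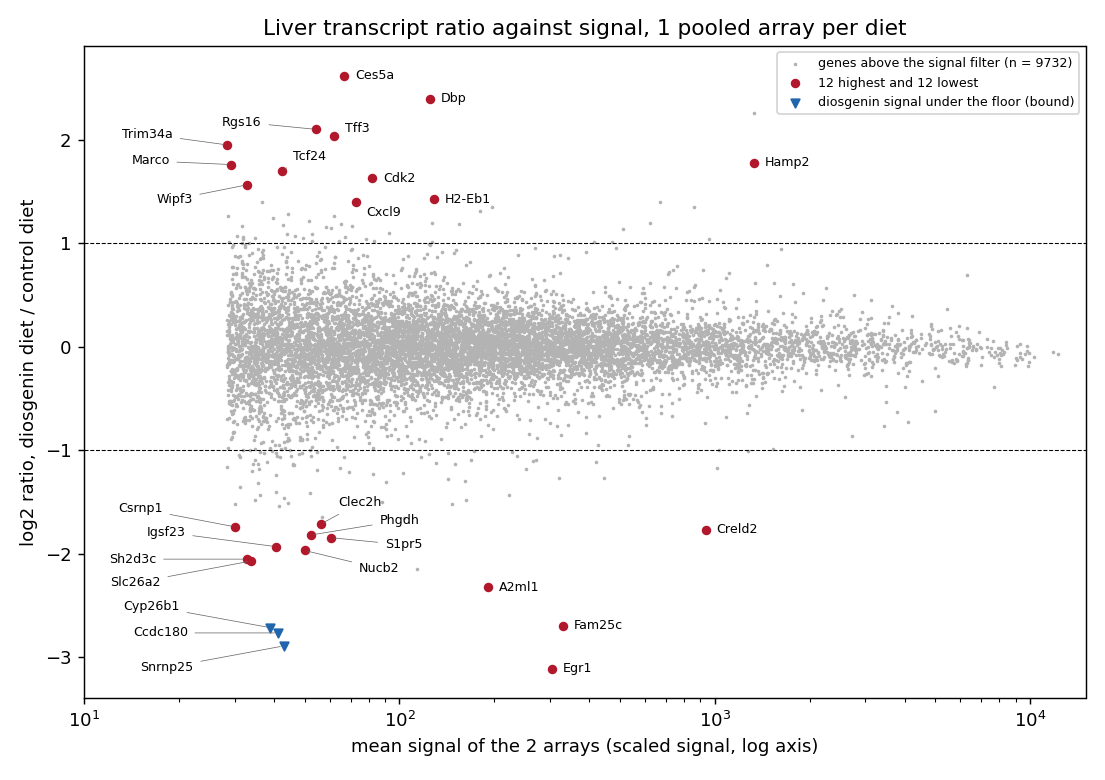
Log2 ratio of the diosgenin array over the control array (vertical axis) against the mean signal of both arrays (horizontal log axis), with a grey point for each of 9732 genes. Red points are the 12 highest and 12 lowest genes, blue triangles are the 3 genes with a diosgenin signal under the floor, and dashed lines mark 2-fold. The spread narrows from dim to bright genes, with Hamp2 and Creld2 standing out at high signal.

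Of the 23 gene lists, 9 stood apart from random lists of matched signal, 6 of them by a higher median and 3 by a lower one. Of the 4 marker lists large enough for a percentile, 3 stood apart, though the call for stellate cell markers depended on the draw of the random lists and was made in 7 of 20 other draws. These draws were added after the data were seen. The amino acid list stood apart in 19 of them, and the other lists and markers that stood apart did so in all 20. The PPARα and female-predominant lists, inside the range here, stood apart in 1 and 4.

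**Figure D2:**
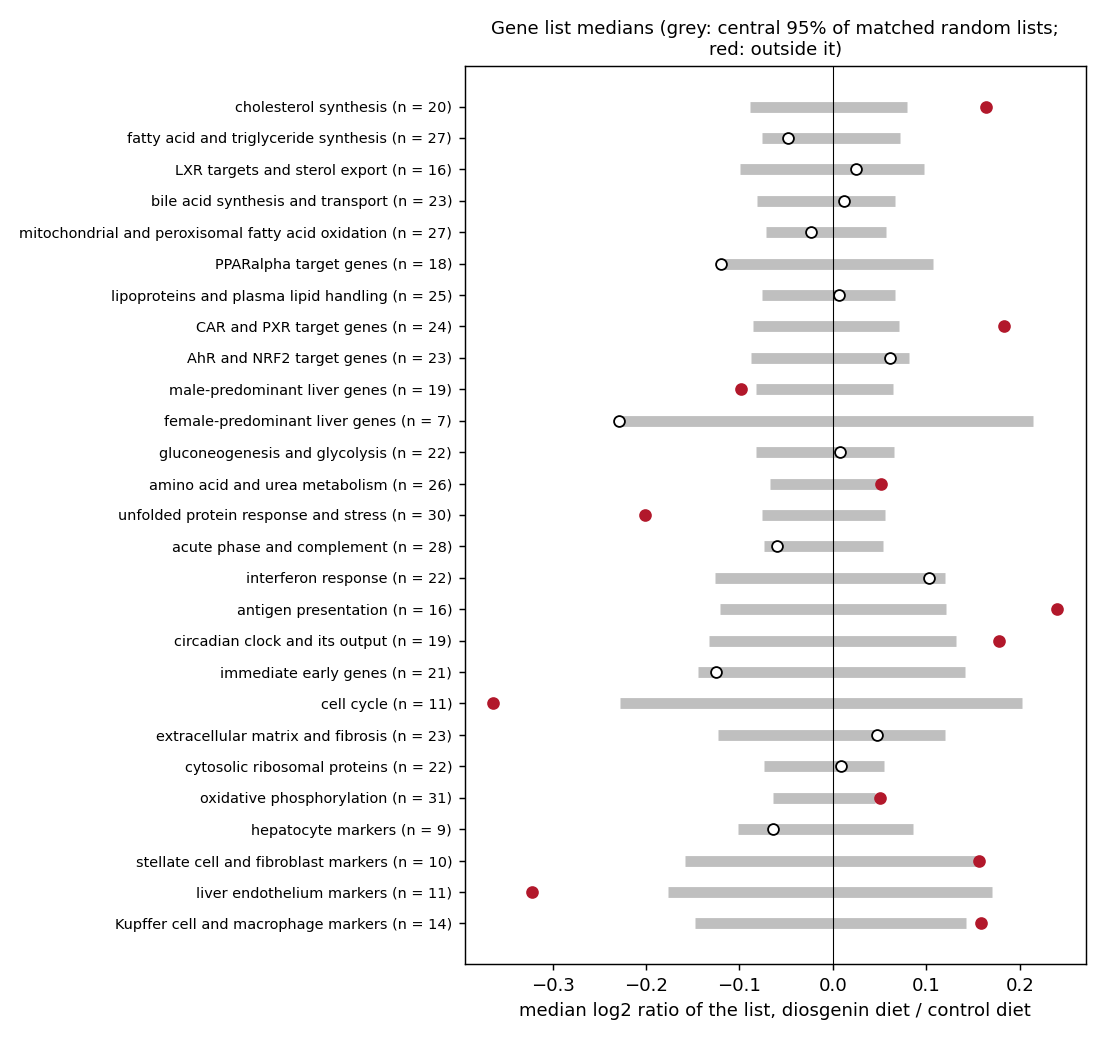
Median log2 ratio (diosgenin over control) of each list with at least 5 genes above the signal filter, with n the number of such genes. Grey bars span the central 95% of 10000 random lists of the same size and signal, filled red points lie outside it and open points inside. Antigen presentation has the highest median, 0.24, and the cell cycle list the lowest, −0.36.

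Genes of cholesterol synthesis were slightly higher as a group. Of 20 genes above the filter 15 were higher and 5 lower, with a median log2 ratio of 0.16, at percentile 99.95 of random lists. The largest ratios were those of the late-pathway enzymes Sc5d and Cyp51, 1.43-fold higher each, followed by the isoprenoid isomerase Idi1 at 1.37-fold, Dhcr7 at 1.21-fold and Sqle, Srebf2 and Lss at 1.16-fold each. Mvd was 1.17-fold lower. No member reached 1.5-fold in either direction. Markers of hepatocytes, the main cell type of the tissue, had a median of −0.06, inside the random range.

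Sterol export and bile acid genes went both ways. The list of LXR targets and sterol export had a median of 0.02 and did not stand apart. Within it Abcg5 and Abcg8, which together form the transporter that moves sterols into bile, were 1.54-fold and 1.35-fold higher. The lipoprotein receptor Scarb1 was 1.34-fold lower and Pltp 1.28-fold lower, the latter by a probe set shared between transcripts. Without shared and alternative probe sets Pltp had a log2 ratio of 0.10. The bile acid list, with 12 genes higher and 11 lower, had a median of 0.01 and did not stand apart. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 2.42-fold lower at 631 against 261, and its other probe sets gave a median of −1.25. The uptake transporter Slco1a4 was 2.48-fold higher, the export pump Abcc2, a family member read by a shared probe set and uncertain, 1.58-fold lower and Akr1d1, a bile acid pathway reductase, 1.46-fold higher.

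Other lipid lists did not stand apart. Fatty acid and triglyceride synthesis had 11 genes higher and 16 lower and a median of −0.05, with Aacs 1.38-fold, Thrsp 1.34-fold and Scd2 1.27-fold lower and the desaturase Fads2 1.30-fold higher. Fatty acid oxidation had a median of −0.02 over 27 genes, with the thiolase Acaa1b 1.31-fold and Crat 1.17-fold lower and Decr2 1.17-fold and Cpt1a 1.16-fold higher. For Crat the median of all its probe sets was 0.13. Of 18 PPARα targets, 13 were lower and 5 higher, with a median of −0.12 at percentile 2.67, just inside the random range. Leaving out shared and alternative probe sets put this list at percentile 1.2, outside it. The pyruvate dehydrogenase kinase Pdk4 was 2.83-fold lower, Cyp4a31 2.75-fold lower and Plin5, uncertain by its shared probe set, 1.39-fold lower, whereas Vnn1 was 1.63-fold higher. With a floor at the 60th percentile the log2 ratio of Cyp4a31 was −1.15. Among lipoprotein genes, whose median of 0.0066 and mean of −0.0022 differed in sign, Tm6sf2 was 1.63-fold higher, lipoprotein lipase Lpl 1.61-fold higher, Apom 1.27-fold higher and Angptl8 1.37-fold lower.

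Targets of the xenobiotic receptors CAR and PXR were higher as a group. Of 24 genes 17 were higher and 7 lower, with a median of 0.18 that none of the 10000 random lists reached. Slco1a4 and Cyp3a13 were 2.48-fold and 2.30-fold higher, Ces2a 1.42-fold and Gstt1 1.41-fold. The sulfotransferases Sult1d1 and Sult5a1 had log2 ratios of 0.58 and 0.53 and the sulfate donor enzyme Papss2 one of 0.57. Gstm3 was 1.40-fold lower by a probe set that can bind several family members and is uncertain. With such probe sets left out its log2 ratio was −0.01. Cyp2b10 and Cyp3a11, named here after their values were seen because they are usual reporters of these receptors, were 1.10-fold and 1.04-fold lower, and the Cyp2b10 probe set is also a shared one. With the median of each gene's probe sets the list median was 0.11, still outside the random range.

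Of the AhR and NRF2 targets 13 were higher and 10 lower. Their median of 0.06 did not stand apart. The glutathione transferase Gsta2 was 1.53-fold higher, heme oxygenase Hmox1 1.49-fold, the metallothionein Mt1 1.47-fold and Tiparp 1.39-fold, where Mt1 and Tiparp were read by shared probe sets and Mt1 is uncertain. Without shared and alternative probe sets the log2 ratio of Tiparp was 0.18.

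Liver genes with higher expression in males were slightly lower. Of 19 genes 16 were lower and 3 higher, with a median of −0.10 at percentile 0.78. The fatty acid elongase Elovl3 was 1.65-fold lower, Moxd1 1.63-fold, Keg1 1.31-fold, Ugt2b38 1.23-fold, Hsd3b2 and Hsd3b5 1.12-fold and 1.11-fold, Cyp7b1 1.11-fold and Mup3, an uncertain family member, 1.10-fold lower. Female-predominant genes were mostly too dim, with 7 above the filter, a median of −0.23 inside the random range and a mean of 0.09, opposite in sign, with Hamp2 the highest member. Cux2 was 1.62-fold lower, Cyp2b9 1.19-fold lower and Rtn4 1.19-fold higher. The Y-linked gene Eif2s3y had signals of 328 and 323, Kdm5d 73.6 and 96.4 and Uty 99.1 and 116. Xist was at 20.5 and 22.2, under the filter on both arrays.

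Gluconeogenesis and glycolysis genes had a median of 0.0074, with 11 higher and 11 lower. The coactivator Ppargc1a was 1.83-fold higher, the aminotransferase Got1 1.67-fold higher and Pfkfb3 1.38-fold higher. Igfbp1 had a log2 ratio of −0.56. Amino acid and urea metabolism had 17 genes higher and 9 lower and a median of 0.05 at percentile 97.6, just outside the random range. Mat1a, which makes S-adenosylmethionine, was 1.31-fold higher, Agxt 1.22-fold, Cbs 1.17-fold and Hal 1.15-fold. The urea cycle enzymes Ass1 and Asl were 1.11-fold and 1.10-fold higher. Ass1 was read at signals of only 89.7 and 99.9, against 1941 and 2140 for Asl, with no other probe set above the filter. Whether its probe set reads the main Ass1 transcript was not tested. Glutamate dehydrogenase Glud1 and the aminotransferase Oat were 1.15-fold and 1.12-fold lower. Of 31 oxidative phosphorylation genes 25 were higher and 6 lower, with a median of 0.05 at percentile 98.3. Its largest ratios were those of Sdhd at 1.12-fold, Atp5c1 at 1.11-fold, read by a shared probe set and uncertain, and Atp5o at 1.10-fold higher. Both medians are small and were inside the random range under 5 and 4 of 11 alternatives. The other floors and centring, counted among the 11, could hardly change either call. Ribosomal protein genes had a median of 0.0087 and did not stand apart. Rpl14 and Rpl12 were 2.09-fold and 1.44-fold higher, at signals of 20.7 and 43.2 and of 37.5 and 53.9. With a floor at the 60th percentile the log2 ratio of Rpl14 was 0.60, under 2-fold. Rpl4 and Rps14 were 1.11-fold lower each, where Rps14 was read by a shared probe set and is uncertain.

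Chaperones and other genes of the unfolded protein response and stress were lower as a group. Of 30 genes 21 were lower and 9 higher, with a median of −0.20, below all 10000 random lists. Creld2 was 3.40-fold lower, Sdf2l1 2.13-fold, Hsph1 and Manf 1.82-fold each, the cytosolic chaperone Hsp90aa1 1.70-fold and Hspa5, the main chaperone of the endoplasmic reticulum, 1.53-fold lower at 6052 against 3946. The heat shock genes Hspa1b and Hspa1a went the other way, 2.06-fold and 1.98-fold higher, and are near-identical copies that are uncertain. Without shared and alternative probe sets the median was −0.12, still below the random range. Pancreatic acinar markers had 2 genes above the filter, with Cela1 1.05-fold lower and Cela3b 1.16-fold higher.

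Of the immediate early genes 13 were lower and 8 higher, with 5 lower and 0 higher by at least 1.5-fold. Their median of −0.13 was inside the random range and their mean was −0.40. Without genes found in several lists, they stood apart at percentile 1.06. Besides Egr1, Fos was 2.91-fold lower, Gadd45a 2.64-fold and Myc 2.26-fold. With a floor at the 60th percentile the log2 ratios of Fos, Gadd45a and Myc were −1.11, −1.05 and −0.80, which leaves Myc under 2-fold. Cell cycle genes were lower in 9 of 11 cases, with a median of −0.36 at percentile 0.2. The replication helicase subunit Mcm2 was 2.07-fold lower, cyclins Ccnd1 and Ccne1 1.54-fold and 1.51-fold, the inhibitor Cdkn1a 1.47-fold, Mcm6 1.40-fold, Mcm4 1.29-fold and Rrm2 1.15-fold lower, and Tk1 was 1.40-fold higher. Mcm2, Mcm4 and Rrm2 were read by shared probe sets and are uncertain. Most of these genes were dim. With the filter at the 75th percentile, only 5 were left, with a median of −0.14 inside the random range. Markers of liver endothelium were also lower, with a median of −0.32.

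Genes of the circadian clock and its output went both ways, with 11 higher and 8 lower and a median of 0.18 at percentile 99.6. The list mixes genes that peak in the light and in the dark phase, so its median depends on how many of each it holds. By phase lists chosen after the values were seen, 8 light phase genes had a median of 0.54 and 4 dark phase genes one of −0.40. Dbp was 5.27-fold higher, the repressor Per1 2.03-fold, Bhlhe40 1.94-fold, the nuclear receptor Nr1d1 1.63-fold and Tef 1.57-fold. Cry1 was 1.83-fold and Usp2 1.39-fold lower, and the activator Arntl had a log2 ratio of −0.58. The median was 0.01 without the signal filter, where the list no longer stood apart, and 0.38 with the filter at the 75th percentile. The hour of collection is not given in the labels used here.

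**Figure D3:**
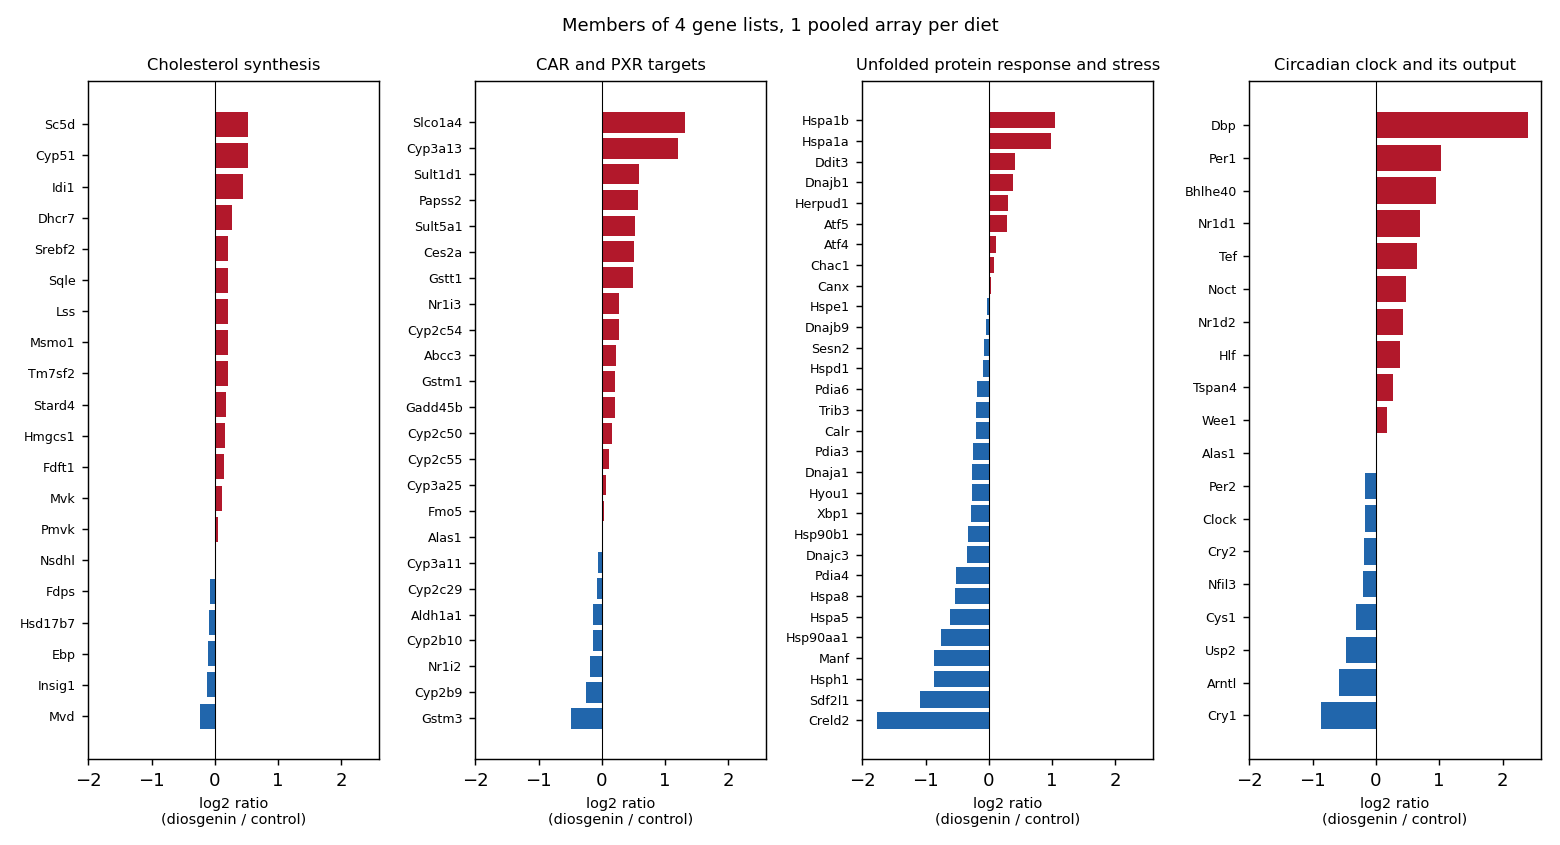
Log2 ratio (diosgenin over control) of every gene above the signal filter in 4 lists, 1 bar per gene from 0, red where higher and blue where lower on the diosgenin array. Slco1a4 and Cyp3a13 lead the CAR and PXR list, Creld2 is the lowest gene of the stress list and Dbp the highest of the clock list.

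Antigen presentation was the list with the highest median. Of 16 genes 13 were higher and 3 lower, with a median of 0.24 at percentile 99.99. The class II genes H2-Eb1 and H2-Ab1 were 2.68-fold and 1.19-fold higher, H2-Aa had a log2 ratio of 0.56, and Cd74 and H2-DMa were 1.34-fold and 1.26-fold higher, where H2-Aa and H2-Ab1 were read by shared probe sets and are uncertain. The median of the H2-Ab1 probe sets was a log2 ratio of 0.53. The transactivator Nlrc5 was 2.10-fold higher at dim signals of 30.1 and 63.3, the immunoproteasome subunit Psmb10 1.46-fold and Tapbp 1.26-fold. The 3 lower genes, named after their values were seen, were Tap1, H2-K1 and B2m, with log2 ratios of −0.14, −0.12 and −0.04. H2-D1 and Tap2 were at 0.06 and 0.01. H2-K1 and H2-D1 were read by shared probe sets and are uncertain, and their other probe sets had medians of 0.23 and 0.27. Interferon response genes had 15 higher and 7 lower and a median of 0.10 at percentile 95.4, which did not stand apart, while their mean was 0.24. Gbp2 was 2.43-fold higher, Xaf1 2.22-fold, Usp18 1.81-fold and Irf9 1.66-fold. Without the signal filter this list stood apart. Markers of Kupffer cells and macrophages were higher beside these lists, in 10 of 14 genes, with a median of 0.16 at percentile 98.4. Marco was 3.39-fold, Lyz2 1.29-fold and Clec4f 1.29-fold higher. With the filter at the 75th percentile their median of 0.12 was inside the random range.

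Acute phase and complement genes had 18 lower and 10 higher, with a median of −0.06 that did not stand apart and a mean of 0.01, opposite in sign. The chemokine Cxcl1 was 2.55-fold higher, Saa3 2.03-fold and Socs3 1.92-fold, and Orm2 was 2.35-fold lower. The median of all Cxcl1 probe sets was a log2 ratio of 0.73, and without shared and alternative probe sets that of Socs3, an uncertain family member, was 0.35. Matrix and fibrosis genes had 14 higher and 9 lower, with a median of 0.05 inside the random range and a mean of −0.04. The contractile genes Acta2 and Tagln were 1.86-fold and 1.67-fold lower, the basement membrane collagen Col4a2 1.56-fold lower and Tgfb1 1.46-fold higher, where Acta2 was read by a shared probe set and is uncertain. Beside them, stellate cell and fibroblast markers had a median of 0.16 at percentile 97.51, at the very edge of the random range and outside it in 7 of 20 other draws, with Pdgfrb 1.31-fold lower and Dcn and Des 1.30-fold and 1.29-fold higher. Genes marking liver endothelium were lower in 10 of 11 cases, with a median of −0.32 at percentile 0.03. Clec4g was 1.61-fold and Lyve1 1.41-fold lower, and Fcgr2b, uncertain by its shared probe set, had a log2 ratio of −0.59.

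Other cell types had few markers above the filter. The 3 cholangiocyte markers were all lower, with Mmp7 1.86-fold, Sox9 1.61-fold and Onecut1 1.18-fold lower. With a floor at the 60th percentile the log2 ratio of Mmp7 was −0.42. Medians were −0.14 for 2 T and NK cell genes, −0.10 for 4 B and plasma cell genes, −0.10 for 3 erythroid genes, 0.07 for 2 acinar genes, −0.02 for 4 adipocyte genes, −0.17 for 3 intestinal genes and 0.23 for 3 Y-linked genes. The adipocyte mean was 0.02, opposite in sign to the median. Skeletal muscle had 1 gene, Atp2a1, 1.60-fold higher, and no neutrophil marker was above the filter.

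RNA quality was similar on both arrays. The 3′ to 5′ signal ratio of the Gapdh control probe sets was 0.82 for control and 0.80 for diosgenin, and that of Actb was 1.86 and 2.03. All 8 spiked control transcripts were lower on the diosgenin array, with log2 ratios from −0.06 for BioC to −0.46 for Dap. Gene values are relative to the scaled signal of each array and not to the spikes.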

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

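No list that stood apart changed sign under the alternatives run. Of the 137 genes at least 2-fold apart, 30 had several probe sets above the filter, and in 25 of these the median of the others had the same sign. Of 1735 alternative values for 183 named genes, 1699 moved by less than the spread between probe sets and 36 by more. Of the 36, 21 came with the floor at the 60th percentile, which compresses dim genes by construction. The 1699 include many values that could hardly move. Other signal filters leave a gene's ratio unchanged, and centring is a constant shift. Lower floors reach only genes with a signal under the main floor, and probe set medians only genes with several probe sets. The 1699 therefore overstate robustness. Of 324 alternative values for 27 lists, 312 moved by less than the random lists' range allows and 12 by more. The 312 include the other floors, which left every list median unchanged, and centring, a constant shift. Genes at least 2-fold higher and lower on the diosgenin diet numbered 180 and 218 with no signal filter, 19 and 32 with the signal filter at the 75th percentile, 276 and 351 at 1.5-fold and 10 and 18 at 3-fold, which follows from the genes and sizes counted. With no signal filter the median was 0 for female-predominant genes, 0.013 for the circadian clock and −0.14 for the cell cycle. With the filter at the 75th percentile these were 0.011, 0.38 and −0.14, and agreement between probe sets was 65.8%. The median of the unfolded protein response list was −0.12 without shared and alternative probe sets. List means were 0.089 for female-predominant genes, 0.013 for the acute phase, 0.24 for the interferon response and −0.40 for immediate early genes. Without genes found in several lists the female-predominant median was 0.011. The cause of these list shifts was not tested.

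Cholesterol synthesis, CAR and PXR targets, male-predominant genes, the unfolded protein response, antigen presentation and liver endothelium stood apart in all 11 alternatives that give a percentile. The circadian clock, the cell cycle and Kupffer cell markers did so in 10, stellate cell markers in 9 and in 7 of 20 other draws of the random lists, a check chosen after the data were seen, oxidative phosphorylation in 7 and amino acid metabolism in 6. The PPARα, female-predominant, acute phase, interferon and immediate early lists stood apart in 1 alternative each and not in the main setting. The other floors left every list median as in the main setting, and centring moves the random lists alike. These alternatives could hardly change a call, so the counts overstate robustness. Apart from them, amino acid metabolism stood apart only with the median of a gene's probe sets and the higher signal filter. Oxidative phosphorylation did so only with quantile normalization, that filter and the omission of genes in several lists, which removed none of its genes. Other scalings left 39.7% to 40.3% of the 2-fold genes higher, against 39.4%. No paired analysis was possible because each diet had 1 array. Of the 137 genes at least 2-fold apart, 82 were among the 2433 dimmest, so for these the signal over background limits what the ratio shows. Without replicate arrays no alternative bears on the spread between mice.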

Other observations

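Carboxylesterases, a family of lipid and drug ester hydrolases, were higher as a family, which was seen in a scan of 146 families sharing a name stem and having at least 8 genes. The family was chosen after its values were seen, and 15 families stood apart where 7.3 would by chance if genes were independent. Genes of a family can vary together, so more could. Of 11 carboxylesterase genes 10 were higher, with a median log2 ratio of 0.24 at percentile 99.96. Ces1g was 1.67-fold higher at 551 against 922, Ces2b 1.55-fold and Ces2a 1.42-fold, and Ces1f, read by a shared probe set, was 1.13-fold lower. In the same scan the Sec genes, many of them parts of the secretory route, had a median of −0.13 with 16 of 24 lower. Genes with names beginning in Irf, not all of them necessarily interferon regulatory factors, had a median of 0.22 with 8 of 10 higher. The Hspa heat shock genes had a median of −0.29 with 5 of 9 lower. The cytochrome P450 genes had a median of −0.06 with 26 of 45 lower, at percentile 2.455, the very edge of the random range. With the carboxylesterases these are 5 of the 15 families. Single genes noted after their values were seen were Dio1, the thyroid hormone deiodinase, at 485 against 1238, 2.55-fold higher, and the repressor Bcl6, 2.79-fold lower with its other probe set at −1.48.

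The other scalings and the filter at the 75th percentile were planned, but their use as tests of the patterns that follow, the clock lists by phase and their difference, the acinar marker test and the difference of Kupffer cell and endothelium markers were chosen after the values were seen. In 2 cases the test was also replaced after its outcome was known. For the clock, agreement between probe sets was tried before the filter on dim genes, and Dbp alone was testable, with 1 of 1 agreeing, which decided nothing. For the acinar cells, the brightest marker was tried before the median of all markers. That marker, Cela1, stood at 1212 on the control array, above the Creld2 difference of 1023, so in that form the explanation was left open.

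Several clock output genes were higher, and Arntl and Cry1 were lower. The list median was at least 0.18 under each of 3 other scalings. Centring moves the random lists alike, and the 3 scalings barely moved the median of all genes. They could hardly have moved the list, and none used the spikes, so they do not settle the question of scaling. The median was 0.38 over the 13 genes left by the filter at the 75th percentile. This argues against noise of dim probe sets for those genes only. With no signal filter the list median was 0.013, inside the random range. The median of 8 light phase genes exceeded that of 4 dark phase genes by 0.94, where random pairs spanned −0.33 to 0.34, with Usp2, at −0.47, going against it. The phase lists restate the pattern, so this difference adds no support for a shift of phase, and an hour of collection that differed and an effect of the diet cannot be told apart, since each pool is a diet and the labels give no hour. Egr1, Per1 and other genes of any list that follow the hour of day or handling are open to the same doubt, which was not tested.

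The unfolded protein response and stress genes were lower as a list, which also holds cytosolic and mitochondrial heat shock genes, while Canx at 0.03, Herpud1 at 0.31 and Hspa1b at 1.04 were not lower. The list median nearest to 0 under other scalings was −0.18, which does not settle the question of scaling, for the reason given for the clock. The median was −0.26 over the 27 genes left by the filter at the 75th percentile, which argues against dim probe sets. Pancreatic tissue in the control pool, rich in such chaperones, would bring its abundant transcripts, but the median control signal of 9 acinar markers was 9.45, under the floor of 10.7, with Ctrb1 at 3.46, Cpa1 at 1.48 and Cpb1 at 0.84. Above the floor were Cela1, at 1212 and 1150 on the control and diosgenin arrays, Cela3b at 38.2 and 44.2, Prss2 at 28.4 and 21.4 and Cel at 18.6 and 15.2. An effect of the diet may remain as a hypothesis, beside the hour of collection, the cage, feeding state and differences between mice. A pool per diet leaves all of these untested.

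The liver endothelium markers were lower by their median, while Kdr, Eng and Cdh5, named after their values were seen, had log2 ratios of −0.06, −0.03 and 0.03. Under other scalings their median nearest to 0 was −0.32, and it was −0.37 over the 9 genes left by the filter at the 75th percentile. As for the clock, the scalings do not settle the question of scaling. A lower share of all non-parenchymal cells would lower the Kupffer cell markers alike, but their median lay above that of the endothelium by 0.48, where random pairs spanned −0.22 to 0.22. Both medians were known when the lists were paired, so this difference restates them and does not decide the question. With the filter at the 75th percentile the Kupffer cell median was inside the random range. Other non-parenchymal markers went both ways, with medians of 0.16 for stellate cells and −0.69 for 3 cholangiocyte markers. A lower share of endothelial cells, lower levels of some transcripts within them, differences between the sampled pieces of liver and differences between the mice or cages may each apply. None of these was tested, and 1 pool per diet leaves them open.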
